A study of Mus musculus with 16 samples.

How the data were processed

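RNA of mouse brain at embryonic day 18 had been labelled with biotin and hybridised to Illumina mouse whole-genome bead arrays in 1 colour, per the labels. The series holds 16 arrays, 8 titled HeCo and 8 titled wild type, and group and array number were taken from the sample titles. The title numbers run through both groups without being shared, so no samples were paired. They come in runs by group: 1 to 4 wild type, 5 to 8 HeCo, 9 to 12 wild type and 13 to 16 HeCo. What the numbers stand for was not given, so any order of handling along these runs cannot be told apart from genotype. The labels name no slide or scan date.

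A table of the whole series was deposited with a signal and a detection p-value for each of 45281 probes and each array. The signals in it are intensities on a linear scale, and neither background subtraction nor normalization by the authors was visible in the deposited values. Each detection p-value deposited by the authors is a multiple of 1/936, the share of negative control beads as bright as the probe; the control signals themselves were not used here. GenomeStudio is named in the submitters' processing notes, with its version not given in the sources used here. The series matrix deposited by the authors holds intensities of the same arrays on a linear scale. They match a quantile normalization of the signals without background correction to within 0.004741 on the log2 scale. All 16 of its columns correlated best with their own array, and the column medians ran from 85.16 to 85.21. Scale and centring of these values are thus settled by the comparison, and they served as an alternative.

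Analyses were run in R 4.3.3 with limma 3.58.1, and plots were drawn in Python 3.11.15 with matplotlib 3.10.9. The signals were background-corrected and quantile-normalized with neqc, with an offset of 16 and the level of the negative controls inferred from the detection p-values, and put on the log2 scale. Probes with a detection p under 0.05 on at least 8 of the 16 arrays were kept (18532 probes). Gene symbols came from the platform annotation, where 34885 probes had 1 gene symbol, 18 had several and 10378 were not listed with a gene. Symbols were updated through the Entrez identifier for the 34807 probes found in a RefSeq gene table of the assembly GRCm38.p6. That table served only for names and for the order of genes, and no coordinates are given, since the build behind the probe design was not given in the sources used here. Of the kept probes, 15983 had a single gene symbol and represented 10624 genes. For the 3773 genes with more than 1 kept probe, the probe with the highest mean over all arrays stood for the gene, which leaves disagreeing probes out of the counts.

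HeCo was compared with wild type by lmFit and eBayes with a mean-variance trend and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes, with a threshold of 0.05. A difference is always HeCo minus wild type on the log2 scale. Background correction with an offset shrinks the differences of dim genes. Where a probe was detected on no array of a group, its fold is given as a bound.

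Gene lists (29, for neuron types, progenitors, glia, other cell types, brain regions, cell division, cilia, stress and the EML family) were fixed before the data were examined, as were the comparison, the alternatives and the rule for named genes. Lists with at least 5 measured genes (28) were tested with camera against all other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. Camera with an estimated correlation, fry, which asks whether a list's genes move on balance in 1 direction or, in its mixed form, in either, and a two-sided exact permutation test of the list's mean on each array (12870 splits, smallest p 0.000155) were run beside it. P-values of a list's members were also adjusted over that list alone, a looser criterion that was not corrected across lists. Genes within 100 positions of Eml1 in the gene order were compared with all others by Fisher's exact test.

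The genes named are Eml1, the genes past the threshold, and of each list the members past the threshold (at most 4) or, with none, the 2 with the smallest p. Because fewer than 10 genes passed, the 10 genes with the smallest p stand in for the first part. Genes outside this rule are named as such where they appear, and the result of 1 probe past the threshold is not reported here.

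The analysis was tested on simulated data with the observed means and spreads of the 10624 genes, 50 genes being changed at each of 4 sizes and the deep-layer list shifted as a whole. At log2 changes of 0.25, 0.5, 0.75 and 1, it recovered 12, 45, 48 and 47 of 50. It called 163 genes in all, 9 of them unchanged. With so many calls the Benjamini-Hochberg cut-off on p is looser than in the data, so these counts overstate the recovery there. In a run without changes it called 0 genes and 0 lists. Each probe was simulated independently of the others, so this run does not test list calls where members are correlated. In the data, the estimated correlation between genes was 0.531 for the diencephalon, midbrain and hindbrain list. Alternatives covered the background correction, the normalization, the detection filter, the authors' normalized values, the probe rule, the variance model, array weights, the title numbers as a block, Y-linked genes as a covariate, the window around Eml1, the thresholds, and each array left out in turn. Added after the data had been seen were the omission of HeCo 7 and HeCo 16, covariates for the mean of the hindbrain and midbrain list, the description number and Xist, a test of every kept probe on its own, and the exact permutation of list means. The direction of a list under an alternative was taken from the sign of its mean, a choice also made after the values were seen.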

Results

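Gene expression was measured in the brain of mouse embryos at embryonic day 18 on 16 single-colour Illumina bead arrays, 8 from HeCo mutants and 8 from wild-type embryos of the same NOR/CD-1 background. HeCo (heterotopic cortex) mice carry a mutation in Eml1, which encodes a microtubule-associated protein, and develop a band of misplaced neurons beneath the cortex. The comparison asks which transcripts differ between mutant and wild-type brain near the end of gestation. The labels do not say that each sample came from a separate animal, so the p-values below measure only the spread between these samples. The mean deposited signal per array ranged from 374.9 (wild type 10) to 597.9 (HeCo 15), and between 17694 and 19553 of the 45281 probes were detected. Normalized signals of the kept probes correlated between arrays with Pearson's r of 0.9757 to 0.9954 across probes, which are not independent replicates. The number of arrays limits the precision of every value that follows.

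Eml1 itself separated the genotypes on every array, and its 2 probes moved in opposite directions. The brighter probe (ILMN_1214866) had a normalized log2 signal of 8.51 ± 0.15 (SD, n = 8) in wild type and 4.51 ± 0.08 (SD, n = 8) in HeCo. It was detected on 8 of 8 wild-type arrays and 0 of 8 HeCo arrays, so that its signal in HeCo was at least 11.4-fold lower (fitted log2 change -4.00, SE 0.08, limma adjusted p = 1.54e-20). The second probe (ILMN_3137207) was detected on 0 of 8 wild-type arrays and 8 of 8 HeCo arrays. It rose from 4.57 ± 0.09 (SD, n = 8) to 6.51 ± 0.37 (SD, n = 8), at least 2.77-fold (log2 change 1.94, SE 0.13, limma adjusted p over all kept probes = 1.47e-09). Each bound sets the mean of the group in which the probe was detected against the mean, over the arrays of the other group, of the lowest normalized signal of any detected probe or the probe's own signal, whichever was higher. The brighter probe stands for the gene in the counts below. Which part of the transcript either probe matches was not given in the sources used here.

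**Figure D1:**
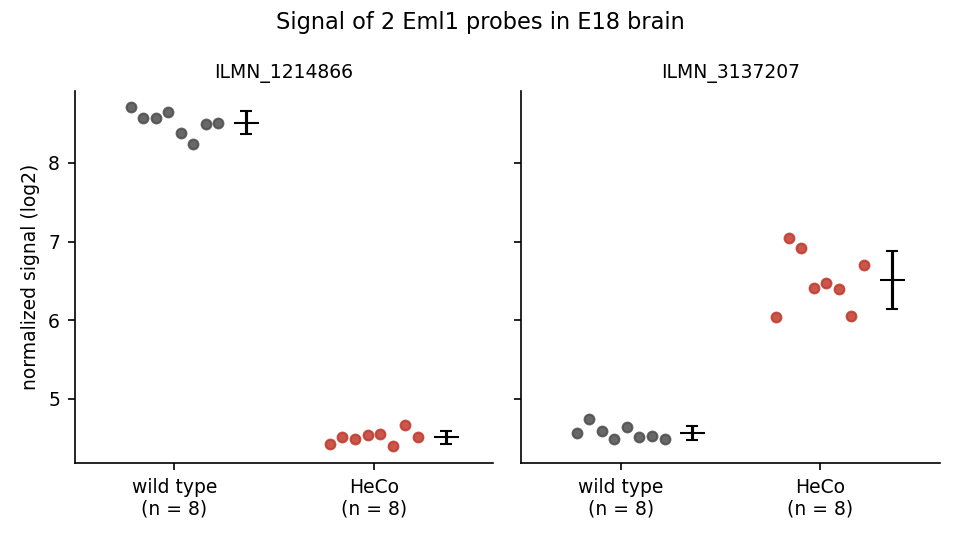
Normalized log2 signal of 2 Eml1 probes (y axis) on each of the 8 wild-type and 8 HeCo arrays (points), with the mean and SD of each group in black. The first probe lies between 8.23 and 8.71 in wild type and between 4.40 and 4.67 in HeCo, and the second between 4.49 and 4.75 in wild type and between 6.04 and 7.05 in HeCo.

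Beyond Eml1, few genes were called. Small changes can be missed, since 12 of 50 simulated genes were recovered at a log2 change of 0.25. Larger ones can be missed too, as Dctn1 (0.63) and Hes5 (-0.49) did not pass in the data. The simulation called 163 genes, which loosens the Benjamini-Hochberg cut-off, so its recovery overstates that in the data. Of 10624 genes tested, 6 passed the threshold, 4 higher and 2 lower in HeCo (66.7% higher; 83.3% after scaling each array to the same median, where Clk1 and Spry3 lost their calls). Ccn2, which encodes a secreted matricellular protein and marks the deepest neurons of the developing cortex, rose 1.61-fold (log2 change 0.69, SE 0.09, limma adjusted p = 0.000255). Its second probe rose 1.57-fold, and no HeCo array overlapped a wild-type array. Acer2, an alkaline ceramidase of the Golgi, rose 1.66-fold (log2 change 0.73, SE 0.12, limma adjusted p = 0.0182). Spry3, a member of the Sprouty family of receptor tyrosine kinase signalling inhibitors, rose 1.41-fold (log2 change 0.50, SE 0.09, limma adjusted p = 0.0192). Wdpcp, a planar cell polarity effector needed for cilium formation, rose 1.43-fold (log2 change 0.52, SE 0.10, limma adjusted p = 0.0397), and its other detected probe was 1.32-fold higher. Clk1, a kinase that phosphorylates splicing factors, fell 1.68-fold (log2 change -0.75, SE 0.13, limma adjusted p = 0.0192). All 8 HeCo arrays lay on the same side of the wild-type mean for each of these genes. Without background correction Acer2 and Wdpcp had smaller differences of 0.45 (SE 0.07) and 0.28 (SE 0.05), with their calls kept.

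The next 4 genes by p-value did not pass. Peli2, an E3 ubiquitin ligase of Toll-like receptor signalling, had a log2 difference of -0.46 (SE 0.09, limma adjusted p = 0.056). Ciart, a circadian transcriptional repressor, had 0.42 (SE 0.08, adjusted p = 0.0664), and its other probe detected on all arrays had 0.50 (SE 0.09). The chromatin reader Phf13 had -0.43 (SE 0.09, adjusted p = 0.0664), and Dctn1, the largest subunit of the dynein activator dynactin, had 0.63 (SE 0.13, adjusted p = 0.0679). At an unadjusted p under 0.05 there were 749 genes, against 531.2 by chance, of which 397 were higher and 352 lower in HeCo. For 12 genes the arrays of both groups did not overlap, where chance would give 1.651 genes (0.01554% of those tested). Only Eml1 and Ccn2 passed without wild type 2, without HeCo 8 or without HeCo 5 (2 genes each), 3 genes passed without wild type 9, and Clk1 did not pass without wild type 12 (difference -0.73, adjusted p = 0.0519, in a range of 0.0038 to 0.197 over all alternatives). Wdpcp passed only without wild type 10, 11 or 12 or HeCo 15 or 16 (highest adjusted p = 0.113, lowest 0.0205), with differences of 0.48 to 0.57 over all arrays left out. Within title numbers 1 to 8 and 9 to 16, each with 4 HeCo and 4 wild-type arrays, 1 and 2 genes passed, and Ccn2 had log2 differences of 0.63 and 0.75. Within sample numbers 1 to 8 and 9 to 16 of the descriptions, along which the deposited background rose, 2 and 1 genes passed, and the differences of Ccn2 were 0.84 and 0.54.

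**Figure D2:**
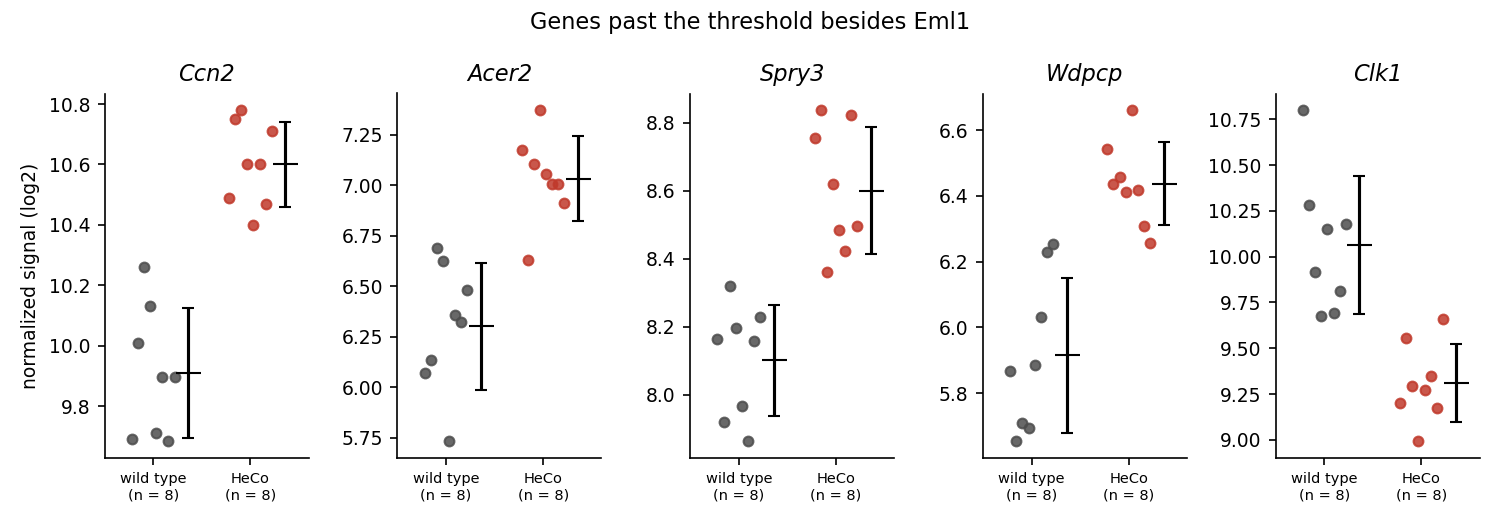
Normalized log2 signal (y axes, each with its own range that does not start at 0) of the 5 genes that passed the threshold besides Eml1, on each of the 8 wild-type and 8 HeCo arrays (points), with the mean and SD of each group in black. Ccn2 lies between 10.4 and 10.8 in HeCo and between 9.68 and 10.3 in wild type, and Clk1 between 8.99 and 9.66 in HeCo and between 9.68 and 10.8 in wild type.

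Markers of deep-layer cortical neurons were higher in HeCo as a group. Of 15 measured genes of this list, fixed in advance, 14 had a positive difference. The mean over all 15 was 0.17 (SE 0.04) on the log2 scale (camera adjusted p = 3.47e-06, and 0.0473 with an estimated correlation). Their median was lower, at 0.0993, so that the mean is raised by the members with the largest differences. Ccn2 rose and no other member passed over all genes tested. Adjusted over the list alone, 4 members passed, all higher. Besides Ccn2 these were Etv1, a transcription factor of layer 5 neurons (log2 difference 0.42, SE 0.10), the thyroid hormone-binding protein Crym (0.28, SE 0.08) and Tbr1, a transcription factor of layer 6 neurons (0.36, SE 0.11). These 3 were named after their values were seen, and the other detected probes of Etv1 had 0.31 (SE 0.12) and 0.15 (SE 0.13). The mean of the list on each array differed between the genotypes by an exact permutation test (two-sided p = 0.000311 over 12870 splits), also without Ccn2 (difference 0.13, exact p = 0.00389) and without HeCo 7 and HeCo 16, where markers of other brain regions were low (difference 0.15, exact p = 0.000666). The difference was 0.17 and 0.16 within the lower and higher title numbers (exact p = 0.0286 each, the smallest that 4 against 4 arrays allow). It was 0.15 and 0.19 within the lower and higher description numbers (exact p = 0.0286 and 0.0571). Markers of upper-layer cortical neurons had a mean difference of 0.06 (SE 0.04) over 16 genes and did not pass (camera adjusted p = 0.158). Their smallest p-values belonged to the LIM transcription factors and cofactors Lhx2 (0.34, SE 0.09) and Lmo4 (0.19, SE 0.07). Lhx2 passed only when adjusted over the list alone (limma adjusted p over all genes = 0.365). The other detected probe of Lmo4 had -0.06 (SE 0.13).

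Lists of progenitors and of their division did not pass. Apical progenitor and radial glia genes had a mean difference of -0.04 (SE 0.03) over 27 measured genes, 19 of them negative (camera adjusted p = 0.213). None passed over all genes, and 3 passed when adjusted over the list alone. The Notch effectors Hes5 (-0.49, SE 0.10, adjusted p over all genes = 0.0804) and Hes1 (-0.37, SE 0.10, adjusted p = 0.269) had lower means in HeCo, with all 8 HeCo arrays below the wild-type mean for each, and Lhx2 had a higher one. Fry's test for changes in either direction passed for this list (adjusted p = 0.0233). Intermediate progenitor genes had a mean of 0.05 over 14 genes (camera adjusted p = 0.213), with 0.24 (SE 0.09) for the somatostatin receptor Sstr2 and -0.20 (SE 0.14) for the proneural factor Neurog2. Cell cycle and mitosis genes had a mean of 0.03 over 34 genes (camera adjusted p = 0.24), with -0.15 (SE 0.08) for cyclin D1 (Ccnd1) and 0.17 (SE 0.10) for cyclin E2 (Ccne2). Without HeCo 7 and HeCo 16 the means of the intermediate progenitor and cell cycle lists were -0.02 and -0.04. Mitotic spindle and centrosome genes had a mean of 0.03 over 34 genes (camera adjusted p = 0.31). Of these Dctn1 alone passed when adjusted over the list alone, and the depolymerizing kinesin Kif2c had -0.15 (SE 0.08). Primary cilium genes had a mean of -0.01 over 31 genes (camera adjusted p = 0.839), with -0.21 (SE 0.07) for Ift88 and 0.17 (SE 0.05) for the brighter probe of Rab8a, whose other detected probe had -0.06 (SE 0.09). Genes mutated in cortical malformations had a mean of 0.02 over 30 genes (camera adjusted p = 0.213), with 0.18 (SE 0.07) for the brightest probe of Dab1, 0.00213 and 0.09 (SE 0.09 each) for its other detected probes, and 0.13 (SE 0.07) for Dcx. The EML family list passed (camera adjusted p = 0.000463; adjusted p = 0.0473 with an estimated correlation) through Eml1. Its median was -0.01, and the other 4 measured members had a mean difference of 0.00456 (exact permutation p = 0.924).

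Genes for the migration and adhesion of neurons had a mean difference of 0.08 (SE 0.05) over 34 genes, 25 of them positive (camera adjusted p = 0.00413; adjusted p = 0.596 with an estimated correlation). No member passed over all genes or over the list alone. The chemokine Cxcl12 had 0.63 (SE 0.17) and the ephrin Efnb2 0.34 (SE 0.12), with all 8 HeCo arrays above the wild-type mean for each. Cxcl12 is given by its brightest probe, and its other detected probes differed by 0.23 (SE 0.18) and 0.13 (SE 0.16). The call of the list was lost without HeCo 15 (mean 0.05, adjusted p = 0.0755, in a range of 0.000587 to 0.0755 over the 16 arrays left out in turn) and with array weights (mean 0.04, adjusted p = 0.116), and the mean was also 0.05 without wild type 10, where the list passed.

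Markers of the diencephalon, midbrain and hindbrain were far lower on 2 of the 8 HeCo arrays. Over 28 measured genes, 27 had a negative difference, and the mean was -0.48 (SE 0.29; camera adjusted p = 1.76e-07; adjusted p = 0.596 with an estimated correlation). No member passed over all genes or over the list alone. The list mean differed from the wild-type mean by -1.91 on HeCo 7 and by -1.61 on HeCo 16, while the other 6 HeCo arrays together differed from wild type by -0.06 (exact permutation p = 0.531). Of the 28 genes, 14 were not detected on HeCo 7 and 12 on HeCo 16, so that these list means are limited by the background. The mean was -0.28 without HeCo 7 and -0.32 without HeCo 16, with the call kept. The list did not pass without both arrays (camera adjusted p = 0.857, in a range of 4.3e-15 to 0.857 over 15 alternatives). Of single genes, named after their values were seen, the dopamine transporter Slc6a3 and the transcription factor Tal1 were detected on all 8 wild-type arrays and on 6 of 8 HeCo arrays, HeCo 7 and HeCo 16 being those without detection. The homeobox gene Irx2 was not detected on HeCo 7 and differed from the wild-type mean by -2.94 on HeCo 16. The neuropeptide Avp (-0.71, SE 0.23) and Hoxb2 (-0.62, SE 0.23) had the smallest p-values of the list but did not follow HeCo 7 and HeCo 16 alone. Avp differed from the wild-type mean by -1.91 on HeCo 7, -1.57 on HeCo 14 and -0.105 on HeCo 16. Hoxb2 was detected on 4 of 8 HeCo and 6 of 8 wild-type arrays, so that its difference is no exact size. Hoxb5 and Hoxa2, named after their values were seen, also varied among the other arrays. The log2 signal of Hoxb5 was 7.6 or higher on wild type 4, 10, 11 and 12 and HeCo 6, and 5.8 or lower on all others. Besides HeCo 7 and HeCo 16, Hoxa2 was not detected on wild type 1, 3 and 9 or on HeCo 5, 8 and 13. Within lower and higher title numbers the list difference was -0.44 and -0.52 (exact p = 0.514 and 0.143). Within lower and higher description numbers it was -0.52 and -0.45 (exact p = 0.143 and 0.543).

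**Figure D3:**
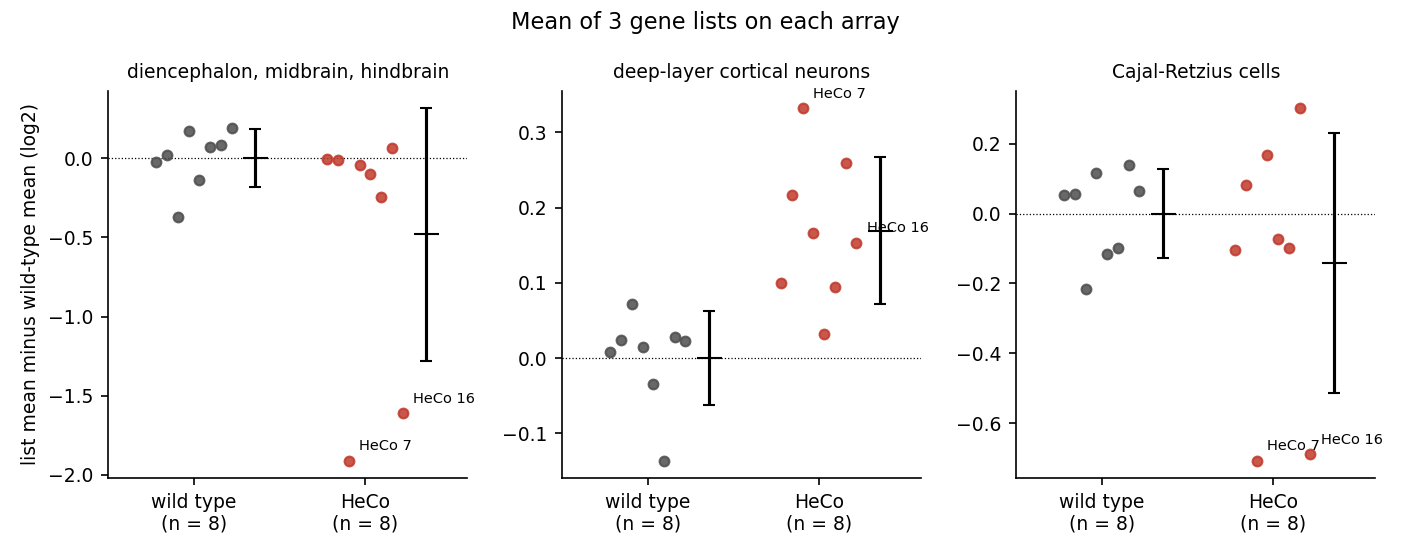
Mean log2 signal of 3 gene lists on each array, less the wild-type mean (y axes, each with its own range), for 8 wild-type and 8 HeCo arrays (points), with the mean and SD of each group in black. HeCo 7 and HeCo 16 lie at -1.91 and -1.61 for diencephalon, midbrain and hindbrain genes, and at -0.71 and -0.69 for Cajal-Retzius genes, while deep-layer genes are 0.33 and 0.15 above the wild-type mean there.

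Other neuronal lists did not pass. Cajal-Retzius genes had a mean of -0.14 (SE 0.14) over 11 genes (camera adjusted p = 0.213). Ebf3 (-0.56, SE 0.34) and Lhx1 (-0.42, SE 0.33) had the smallest p-values, and both were above wild type in mean without HeCo 7 and HeCo 16 (0.06 and 0.16). Cortical interneuron genes had a mean of 0.03 over 19 genes (camera adjusted p = 0.548), with 0.20 (SE 0.09) for Prox1 and 0.27 (SE 0.13) for Sp8. Hippocampus and dentate gyrus genes had a mean of 0.05 over 12 genes (camera adjusted p = 0.213), led by Prox1 and Lef1 (0.21, SE 0.12, detected on 6 of 8 HeCo and 3 of 8 wild-type arrays). Striatum genes had a mean of 0.00333 over 17 genes (camera adjusted p = 0.839), with -0.25 (SE 0.09) for the dopamine receptor Drd2 and 0.13 (SE 0.09) for Foxp1. Synapse and neuronal maturation genes had a mean of 0.01 over 27 genes, with a median of -0.00419 (camera adjusted p = 0.839). There the vesicular glutamate transporter Slc17a7 had 0.38 (SE 0.13) and the scaffold protein Homer1 0.19 (SE 0.07).

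Among lists of other cell types, the meninges passed in the camera test alone. Its 23 measured genes had a mean of 0.10 (SE 0.10), 18 of them positive (camera adjusted p = 0.0119; adjusted p = 0.753 with an estimated correlation), and no member passed over all genes or over the list alone. The small proteoglycans Ogn (0.29, SE 0.12) and Dcn (0.21, SE 0.10) had the smallest p-values. The call was lost without wild type 11 (mean 0.04), wild type 1 (0.06), HeCo 16 (0.07) or wild type 9 (0.07; highest adjusted p = 0.258, lowest over the 16 arrays left out in turn 0.000203), and without both HeCo 7 and HeCo 16 the mean was 0.04 (adjusted p = 0.55). Within the higher description numbers the list mean was -0.07, against 0.26 within the lower. Microglia and macrophage genes had a mean of 0.06 over 18 genes and did not pass (camera adjusted p = 0.0932), with 0.17 (SE 0.07) for Laptm5 and -0.22 (SE 0.12) for Cyba. Astrocyte genes had a mean of -0.04 over 16 genes (camera adjusted p = 0.422), with -0.18 (SE 0.08) for Aldh1l1 and -0.14 (SE 0.08) for Aldoc. Oligodendrocyte lineage genes had a mean of -0.05 over 15 genes (camera adjusted p = 0.839), with 0.26 (SE 0.08) for the transcription factor Sox10 and -0.35 (SE 0.14) for the myelin gene Mag. Ependyma and motile cilia genes had a mean of -0.05 over 17 genes (camera adjusted p = 0.31), with -0.42 (SE 0.16) for Tppp3 and -0.22 (SE 0.10) for Ccdc40, detected on 4 of 8 HeCo and 7 of 8 wild-type arrays. Choroid plexus genes had a mean of 0.04 over 16 genes (camera adjusted p = 0.213), with -0.26 (SE 0.11) for Rdh5 and 0.20 (SE 0.12) for Clic6. Endothelial and pericyte genes had a mean of 0.01 over 24 genes, with a median of -0.01 (camera adjusted p = 0.842). Among them were Sox18 (-0.30, SE 0.10) and the glucose transporter Slc2a1 (0.31, SE 0.11). Red blood cell genes had a mean of -0.03 over 11 genes, with a median of 0 (camera adjusted p = 0.632), and included Tmcc2 (-0.33, SE 0.14) and Cited4 (-0.23, SE 0.12, detected on 5 of 8 HeCo and 7 of 8 wild-type arrays).

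Of the stress and activity lists, that for endoplasmic reticulum stress passed in the camera test. It had a mean of 0.05 (SE 0.03) over 21 genes, 15 of them positive (camera adjusted p = 0.0156; adjusted p = 0.377 with an estimated correlation). No member passed over all genes, and the co-chaperone Dnajc3 (0.27, SE 0.07) passed when adjusted over the list alone, while the disulfide isomerase Pdia6 had 0.18 (SE 0.06). The call was lost without HeCo 14 (mean 0.04), HeCo 13 (0.04) or wild type 11 (0.05; highest adjusted p = 0.0819, lowest over the 16 arrays left out in turn 0.00338). Hypoxia and glycolysis genes had a mean of 0.04 and a median of -0.01 over 25 genes (camera adjusted p = 0.278). The histone demethylase Kdm3a (0.26, SE 0.07) passed only when adjusted over the list alone (limma adjusted p over all genes = 0.314). Immediate-early genes had a mean of 0.02 over 15 genes (camera adjusted p = 0.596). Adjusted over the list alone, Egr1 (0.37, SE 0.11) was higher and Ier3 (-0.35, SE 0.10) lower, but neither passed over all genes (limma adjusted p = 0.377 each). Fry's test for changes in either direction passed for the list (adjusted p = 0.00236). The p53 targets had a mean of -4.47e-05, a median of 0.03 and a camera test in the upward direction over 21 genes (camera adjusted p = 0.839), with -0.21 (SE 0.10) for Eda2r, detected on 7 of 8 arrays of each group, and -0.14 (SE 0.09) for Plk3.

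Of the 28 lists tested, 6 passed camera with the preset correlation, and 2 of these, the deep-layer neurons and the EML family, also passed with an estimated correlation. The same number of lists passed fry's directional test and the exact permutation of list means. Fry's test for changes in either direction passed for 6 lists: deep-layer neurons, the EML family, apical progenitors, immediate-early genes, endoplasmic reticulum stress (adjusted p = 0.00599) and hypoxia and glycolysis (adjusted p = 0.0112).

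**Figure D4:**
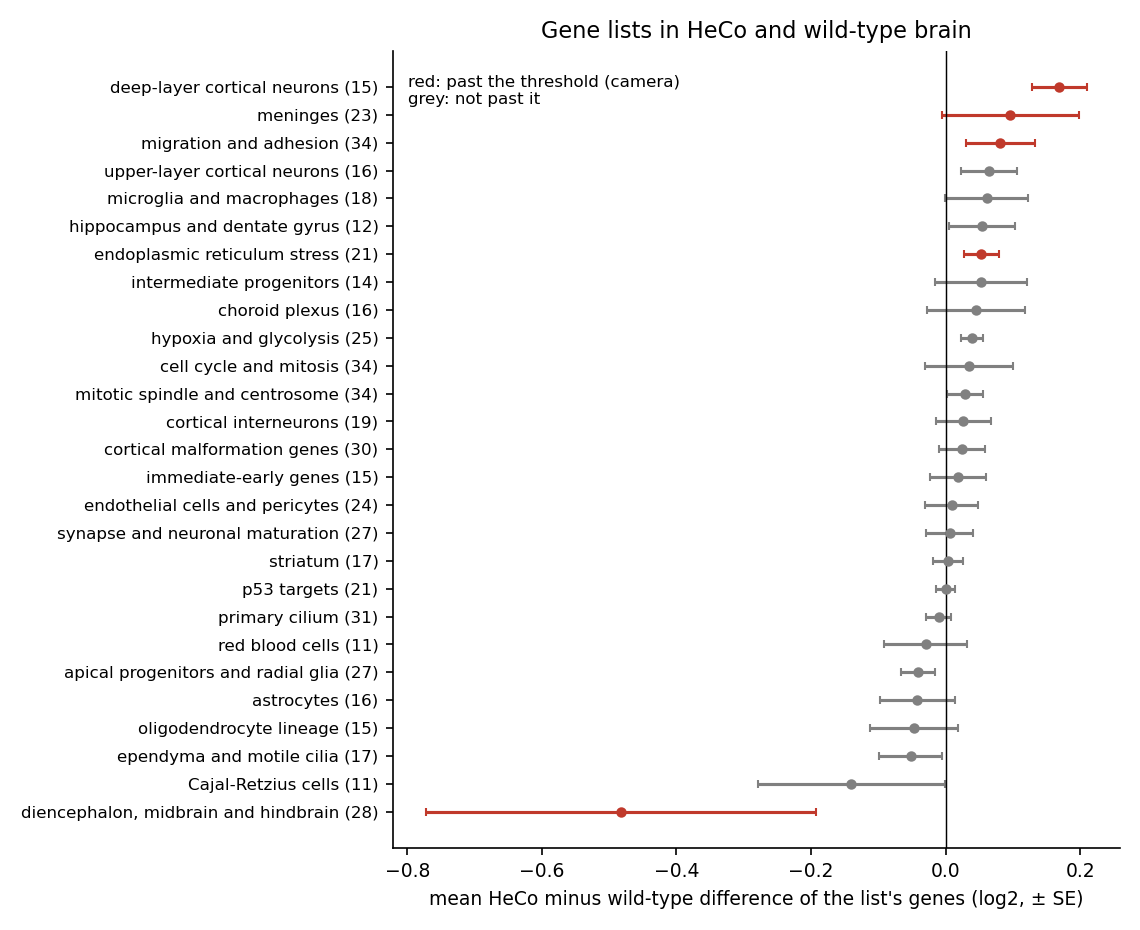
Mean difference between HeCo and wild type over the measured genes of each list (x axis, log2, with the standard error over 8 and 8 array means), with the number of measured genes in parentheses and the EML family left out for scale. Deep-layer genes lie highest, at 0.17, and diencephalon, midbrain and hindbrain genes lowest, at -0.48; lists in red passed camera with the preset correlation.

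Genes beside Eml1 on chromosome 12 were examined because mutant and wild-type chromosomes can differ around a mutation. Of the 100 genes on each side, 20 were measured and none was called by limma, against 5 of 10603 genes elsewhere (Fisher's exact test, two-sided p = 1), while 2 of the 20 had an unadjusted p under 0.05. On the whole chromosome, 25 of 359 other measured genes (6.96%) had an unadjusted p under 0.05, against 7.04% on other chromosomes (Fisher's exact test, two-sided p = 1). Calls were so rare elsewhere that none would be expected among the 20 neighbours, and most neighbours were not measured. The test of called genes therefore does not exclude a local difference. The list of sex-linked genes had 3 measured members, too few for the list test. Xist, which is expressed from the inactive X chromosome of females, had a difference of -0.86 (SE 0.86), with high signals on 4 of 8 HeCo and 6 of 8 wild-type arrays. The Y-linked gene Uty, detected on 7 of 8 HeCo and 8 of 8 wild-type arrays, had -0.09 (SE 0.14). The Uty probe was thus also detected on the wild-type arrays with high Xist, so that it does not tell the sexes apart.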

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

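The 11 results below were picked out by a gap between samples, and no test of an explanation was chosen for them after they were seen. Over 99 named genes and gene lists, the mean signal and the number of detected probes, 11 of 202 groups of 8 arrays held a sample that stood apart from the other 7, its gap to the nearest exceeding Dixon's 95% critical share of the group's range. Chance alone would give about 10.1 such cases, 1 in 20, and no test was run on them as a set.

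Wild type 10 stood apart for 4 measures. It had the fewest detected probes (17694), and its values differed from the median of the other wild-type arrays by -0.829 for the glucose transporter Slc2a1, by 0.639 for Tmcc2 of the red blood cell list and by -0.23 for the migration and adhesion list. HeCo 15 had the highest mean signal (597.9), and it lay -0.655 from the other HeCo arrays for Hes5 and -0.524 for Ier3. HeCo 6 lay 3.68 above the other HeCo arrays for Hoxb5, a gene of the posterior hindbrain and spinal cord, which also varied among wild-type arrays (SD 2.04, n = 8). Hoxb5 was detected on 2 of 8 HeCo arrays, so that this difference is taken mostly against background and is no exact size. HeCo 6 also lay -0.256 from the others for Dnajc3. HeCo 8 was apart for Peli2 (-0.5), and wild type 4 for Sox10 (0.456).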

How the results depend on the processing

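The omission of HeCo 7 and HeCo 16, the covariates for hindbrain genes, description number and Xist, the test of every probe and the list permutation were chosen after the results were seen. The Eml1 level by its brighter probe stayed lower, with its call, in every setting that used it alone (-4.04 to -2.46, no exact fold). The mean of both probes, set by background in both groups, gave -1.03, and the second probe alone was higher (1.94, no exact fold); a detection p under 0.01 on all 16 arrays left out Eml1 and left too few EML genes. Over 16 settings without single arrays left out, Ccn2 kept its call in 16 (0.63 to 0.76), Acer2 in 16 (0.45 to 0.78) and the deep-layer list in 16 (0.14 to 0.23). Without background correction Peli2 had -0.29, Ciart 0.24 and the hindbrain list -0.28 (-0.31 without a filter). Scaling to the same median gave 0.14, 0.15 and 0.11 for the migration, meninges and stress lists. Clk1 and Spry3 were lost there (adjusted p = 0.197 and 0.461, lowest over settings 0.0038 and 0.00559), where the median difference over all genes was 0.048. Their differences there were -0.69 (SE 0.15) and 0.56 (SE 0.14), against -0.75 (SE 0.13) and 0.50 (SE 0.09). Wdpcp was lost without a detection filter, without HeCo 7 and HeCo 16, and with the description number or Xist as a covariate (adjusted p = 0.0548 to 0.075, lowest 0.00983), with differences of 0.51 to 0.55 (SE 0.10 to 0.11) against 0.52 (SE 0.10), in a range of 0.28 to 0.57. Peli2 passed in 11 settings (adjusted p = 0.0126 to 0.595), Ciart in 7 (0.00585 to 0.279), Dctn1 in 2 (0.0367 to 0.296) and Phf13 in 0 (0.0571 to 0.706). The hindbrain list was also lost with a detection p under 0.01 on all arrays (-0.23, adjusted p = 0.0936, range 4.3e-15 to 0.857), the meninges with the hindbrain list or Xist as a covariate (adjusted p = 0.473 and 0.129, range 0.00346 to 0.55), and the stress list without a filter or with Xist (adjusted p = 0.069 and 0.0561, lowest 0.00408). No gene near Eml1 was called by limma in any setting, also with 50 or 200 genes on each side (2 at an unadjusted p under 0.05 with 100). The slide as a block was not run, as no slide was named. No paired analysis was possible because the groups share no title numbers; title numbers 1 to 8 against 9 to 16 as a block changed no call. Covariates made from Xist or the hindbrain list give no value for these. Signal over background limits these results: 39.08% to 43.18% of probes were detected.

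The count of 6 changed genes became 10 with the mean of a gene's detected probes, 2 at an adjusted p under 0.01 and 16 for every detected probe on its own. The 4 higher genes became 7 with the mean of probes. The 2 lower genes became 1 under scaling to the same median, and 4 with array weights, without HeCo 7 and HeCo 16, or with the hindbrain list as a covariate. The 6 lists became 2 by camera with an estimated correlation, 2 by fry and 2 by exact permutation of list means. With single arrays left out, 2 to 7 genes changed, 1 to 5 higher and 1 to 3 lower, and 4 to 8 lists passed. Acer2 was lost without wild type 2, HeCo 8 or HeCo 5 (adjusted p = 0.0588, 0.0623 and 0.0664, lowest 0.00483), as were Clk1 and Spry3 there (0.0588, 0.0623 and 0.0717) and without wild type 9 (0.0676). Acer2 then had 0.68 to 0.71 (SE 0.12 to 0.13), Clk1 -0.74 to -0.71 (SE 0.13 to 0.14) and Spry3 0.47 to 0.50 (SE 0.09). Gained were Hes5 without wild type 11 (adjusted p = 0.0349), Ciart and Dctn1 without HeCo 6 (0.0139 each), Peli2 without HeCo 16, HeCo 7 or wild type 10 (0.0393 to 0.0491), microglia without HeCo 6, wild type 12, wild type 3, wild type 10 or HeCo 15 (0.00767 to 0.0416), choroid plexus without wild type 4 or HeCo 15 (0.0476 and 0.0242) and Cajal-Retzius genes without HeCo 15 (0.0242). The highest adjusted p of these over all settings were 0.235, 0.279, 0.296, 0.595, 0.694, 0.759 and 0.718.

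Apart from single arrays left out, list means turned in 45 cases and named genes in 8; the cause was not tested. Calls of named genes were gained in 23 cases and lost in 6, and those of lists gained in 2 and lost in 8. Gained were microglia with array weights (adjusted p = 0.0355, range 0.00767 to 0.694) and cell cycle genes with the hindbrain covariate. Without HeCo 7 and HeCo 16, values turned to 0.0562 for Ebf3, 0.156 for Lhx1 and 0.0202 for Irx2, and list means to -0.0168 for intermediate progenitors, -0.0355 for cell cycle, -0.0141 for interneurons, -0.0111 for striatum, 0.0458 for Cajal-Retzius, 0.0275 for oligodendrocytes, -0.0127 for endothelium and -0.0079 for immediate-early genes. With the hindbrain and midbrain list as a covariate they turned to 0.129 for Ebf3, 0.231 for Lhx1, 0.00645 for Uty, 0.118 for Irx2 and 0.0167 for Tal1. List means then turned to -0.0347 for intermediate progenitors, -0.0496 for cell cycle (adjusted p = 0.048, range 0.048 to 0.975), 0.00157 for primary cilium, -0.0171 for interneurons, -0.00974 for striatum, 0.0748 for Cajal-Retzius, 0.00191 for astrocytes, 0.0415 for oligodendrocytes, -0.0126 for endothelium and -0.013 for immediate-early genes. Scaling to the same median gave 0.0138 for apical progenitors, 0.0455 for primary cilium, 0.0125 for astrocytes, 0.012 for oligodendrocytes, 0.00194 for red blood cells and 0.0542 for p53 targets. The p53 mean turned to 0.000622 without background correction, 0.000615 with normexp at an offset of 50, 0.00522 without a filter, 0.00453 with detection p under 0.01, 0.00065 with the authors' values, 0.00277 with the mean of probes, 0.000609 with the description number and 0.00317 with Xist. The synapse mean turned to -0.002 without background correction and with the authors' values, -0.00126 with normexp, -0.00289 with cyclic loess and -0.00443 with Xist. The striatum mean turned to -0.00337 with cyclic loess, -0.000993 without a filter, -0.000475 with detection p under 0.01, -0.00127 with the mean of probes, -0.00826 with array weights and -0.000191 with Y-linked genes. Immediate-early genes turned to -0.00543 without a filter and endothelium to -0.00238 with detection p under 0.01. With single arrays left out, means ranged from -0.00566 to 0.0143 for striatum, -0.00618 to 0.0314 for endothelium, -0.00782 to 0.00738 for p53 and -0.00632 to 0.0282 for synapse genes.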

Other observations

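The tests of the tissue share behind the regional markers, of the genotype in the other mutants and of mislabelled samples, the 3 gene lists for Notch, clock and glucocorticoid genes, and the omission of HeCo 7 and HeCo 16 were chosen after the results they bear on had been seen.

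Some transcripts differed between genotypes at probes that do not stand for a gene in the counts above. Of 18532 kept probes tested on their own, 16 passed, 10 higher and 6 lower in HeCo. ILMN_1229073, which has no gene in the annotation used here, was different by -2.69 (SE 0.10, limma adjusted p = 4.96e-14) and detected on all arrays of both groups. ILMN_2838372, also without a gene, was higher by 0.57 (SE 0.11). A dim probe of Marf1, which encodes an RNA-binding regulator of oocyte meiosis, was detected on 1 of 8 wild-type and 8 of 8 HeCo arrays and passed (fitted difference 1.37, mostly against background and so no exact size), while the brightest Marf1 probe differed by 0.05 (SE 0.07). Probes of Klhl5 (0.60, SE 0.11) and St6galnac2 (-0.68, SE 0.13) also passed, although Klhl5 was detected on 7 and ILMN_2838372 on 3 of 8 wild-type arrays, and St6galnac2 on 6 of 8 HeCo arrays, so that these are no exact sizes. A probe of Ciart (0.50, SE 0.09, limma adjusted p over probes = 0.0319) and that of Peli2 (-0.46, SE 0.09, limma adjusted p over probes = 0.0456) passed too, while neither gene passed over genes. Besides the 2 Eml1 probes, another Ciart probe was the only kept probe detected on all arrays of 1 genotype (HeCo) and none of the other, at least 1.13-fold higher (limma adjusted p over probes = 0.0548). These genes were named after their values were seen.

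HeCo 7 and HeCo 16 were alike in other lists too, which was not shown to be separate from their low regional markers. Cajal-Retzius genes lay at -0.71 and -0.69 from the wild-type mean on these arrays, while cell cycle genes lay at 0.26 and 0.23 and intermediate progenitor genes at 0.27 and 0.25. The Cajal-Retzius list shares Barhl2 with the regional list, and its difference was 0.0748 with the regional list mean as a covariate. Its low values there thus followed the regional markers and do not by themselves show fewer Cajal-Retzius cells. Without these arrays 8 genes were called, 5 of them shared with the 6 of all arrays: Hes5, Peli2 and the serine protease-like gene Prss35 passed, and Wdpcp did not. For Hes5 the difference was then -0.57 (adjusted p = 0.0302, in a range of 0.0129 to 0.197 over 16 alternatives).

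The count of 6 genes was the highest among 100 splits of the 16 arrays into 8 and 8, the real split included. Among them 1 split, the real grouping, gave as many, the highest other gave 4, and 98 of the others gave 0. The count of 6 includes Eml1, the mutated gene, which only the real grouping separates. It fell to 2 without wild type 2, HeCo 8 or HeCo 5, below the highest other split. The splits thus bear on the count as a whole, Eml1 included, and do not exclude chance for any single gene.

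Low diencephalon, midbrain and hindbrain markers on HeCo 7 and HeCo 16 may reflect how much of these regions the samples held. On both arrays, 23 of the 28 measured genes lay below all 8 wild-type arrays, but the arrays were singled out by this list, so that the count restates the pattern and does not bear on its source. The other 6 HeCo arrays differed from wild type by -0.0557 (95% interval by inverted exact permutation -0.23 to 0.13). This argues against a fall of the list in every mutant as large as that on HeCo 7 and HeCo 16. A smaller effect of genotype is not excluded, since these 6 remained after 2 arrays had been singled out by the same list. Nor does the list mean bear on single members. A general loss of signal on these arrays is argued against by the number of detected probes, which was 18905 on the lower of the 2 and within the range of the other 14. This count does not measure RNA quality, and a fault that touched only part of the transcripts is not excluded by it. Less tissue of these regions and a regional defect in those 2 embryos cannot be told apart, as the labels name the tissue only as brain.

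Higher deep-layer markers with Ccn2 in HeCo were set against 3 explanations. The 2 samples low in hindbrain markers do not account for the difference, which was 0.145 without them (exact permutation p = 0.000666). Nor does Ccn2 alone, since the list without it gave an exact permutation p of 0.00389. Sex as the source of the Ccn2 change is argued against by its value with Xist as a covariate, 0.677 (SE 0.09). A different makeup of the tissue within the other 14 samples was not tested by these values, though the regional genes Hoxb5 and Hoxa2 varied among them. A change in the number or maturation of deep-layer neurons in mutants is a hypothesis that may be followed up.

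Opposite changes of the 2 Eml1 probes were found on every array, and 0 arrays had a signal of either probe in the range of the other genotype, which speaks against a mislabelled sample. The step of background correction and normalization is argued against, since the deposited signals, taken before it, already differed in opposite directions by more than their spread, with ratios of 5.35 and 1.97 that include background and are no folds of transcript. Whether an altered Eml1 transcript, a variant under a probe or hybridisation to another transcript could give this pattern cannot be told apart: each of the 2 probes was detected in 1 genotype only, and no probe sequence was at hand. The mutation itself therefore stays among the open explanations.

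Hes5 and Hes1 are targets of Notch signalling, and lower expression of the pathway's genes was tested as a hypothesis. Without these 2 genes, the 21 measured genes of a Notch list had a mean difference of -0.000544 (95% interval -0.05 to 0.05, exact permutation p = 0.985, camera p = 0.95). These members went both ways, 11 positive and 10 negative, with -0.26 (SE 0.11) for Psen2 and -0.20 (SE 0.08) for Nrarp against 0.24 (SE 0.10) for Heyl, none of them past the threshold over all genes. The interval of the mean argues against a fall of the list as a whole as large as that of Hes5 (-0.49) or Hes1 (-0.37). The list holds components of the pathway besides its targets, so its mean does not measure Notch signalling, and lower signalling was not tested. A mean near 0 over such members does not bear on single ones, and the interval of Psen2 reached -0.473, so that lower expression of part of the pathway stays open. For the higher Ciart, a shift in clock phase may be considered: 13 other clock genes gave a mixed fry p of 0.356 (exact permutation p of their mean 0.508), with -0.23 (SE 0.10) for Bhlhe40 and 0.20 (SE 0.09) for Per2. The tests of all 3 lists had first taken a p of 0.05 or more as enough to set the explanation aside, which was wrong, since such a p bounds no shift. The bound on single members used in its place was set after the results were seen, and as the interval of a single clock gene reached a size of 0.417, against 0.42 for Ciart, the question stays open. Klf9, Txnip and Bcl6, responsive to glucocorticoids, had differences of 0.49 (SE 0.13), 0.30 (SE 0.07) and 0.57 (SE 0.14) without passing over all genes. The 18 other measured genes of a glucocorticoid list had a mean of 0.05, 13 of them positive (camera p = 0.0966, exact permutation p = 0.153, 95% interval of the mean -0.02 to 0.12). The interval of the mean argues against a common shift of these genes as large as that of Txnip (0.30). A smaller common shift is neither shown nor excluded, and a change of single members stays open, as the interval of 1 member reached 0.514.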
